A study of Caenorhabditis elegans with 4 samples.

How the data were processed

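Chromatin immunoprecipitation followed by sequencing (ChIP-seq) was used to locate the binding regions of HAM-1 in Caenorhabditis elegans larvae of the fed first larval stage (L1). HAM-1 is a winged-helix protein known for its part in the asymmetric division of neuroblasts. The strain, OP102, carries a ham-1 transgene with an EGFP and FLAG tag in an unc-119 mutant background, with unc-119 as the rescue marker. Per the labels' protocols, worms were grown at 20 °C on HB101 bacteria, crosslinked in 2% formaldehyde and sonicated, and the tagged protein was collected with anti-GFP antibody. A part of each extract was kept before the immunoprecipitation as input. The series holds 4 libraries, 2 HAM-1 ChIP libraries and 2 inputs, numbered replicate 1 and replicate 2 in the labels. Nothing in the labels says whether the replicates came from separate cultures.

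The values analysed were 3 lists of binding regions deposited by the authors: one for each ChIP replicate and one described as combined. Per the file headers and source column, the regions were called with PeakSeq, a caller that scores a ChIP library against a control, and are given on the WormBase WS220 genome. Each region has a start, an end and a q-value as the authors' caller gave it, and no height, fold enrichment or read count. All q-values lie under 0.01. The aligner, the version and settings of the caller, the way the replicates were combined and the use of the inputs are not given in the sources used here. Comment lines in the lists record that positions had been moved to WS220 from an earlier build that they do not name, and that the structure of 8 combined, 6 replicate 1 and 2 replicate 2 regions changed in that step. No read totals were used here, so sequencing depth is unknown and no comparison could be scaled by it. A q-value depends on depth as well as on binding, so q-values were used to rank regions within a list, and a lower q-value in one list than in another is not a measure of stronger binding. Inputs have no list of their own here and entered no comparison.

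Positions are 1-based WS220 coordinates as the lists give them. Regions of 2 lists counted as shared when they overlapped by 1 bp or more. Each observed overlap was set against 1000 random placements of the other list's regions on their own chromosomes with widths kept, and the one-sided permutation p cannot fall below 0.001. Random placement takes no account of open chromatin, mappability or gene density. Ranking was compared over regions that were each other's greatest overlap, with Spearman's rho and 100000 permutations. Chromosome lengths were not part of the lists, so the span from position 1 to the last called base in any list stood for the length of each chromosome. Shares of regions per chromosome were tested with two-sided exact binomial tests against the share of span, adjusted by the Benjamini-Hochberg method over the 6 chromosomes. Each span was divided into 3 equal parts, and the outer parts stood for the chromosome arms. Confidence intervals of shares are 95% Wilson intervals. They, the binomial and Fisher tests, the random placement tests and the permutation test of recovery by chromosome treat regions as independent, which neighbouring regions are not. All of these cover counting error only, and recovery was compared within a single pair of libraries. Regions in the 3 lists are not independent of one another either, since the combined list draws on both replicates.

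The only gene table at hand was of assembly WBcel235, a later build than WS220 and without strand. Its positions were not compared with the regions. It served only for the number of protein-coding genes per chromosome. Planned comparisons with promoters, with gene lists and with the sequence at region centres were therefore not run, and the regions are reported by position rather than by gene. The reported single regions are the 10 combined regions with the lowest q-values that overlapped both replicates, a rule fixed before the data were examined. Also fixed then were the tests of overlap, ranking, support in both replicates, X share and arm share, and most alternatives: a 50% reciprocal overlap, the stronger 50% of each list by q-value, lists cut to equal length, regions in both replicates, each replicate's own list, and gene number as background. The comparison of X with the autosomes, the tests of the other chromosomes, the spacing and 1 Mb counts, the recovery by rank and by chromosome, the strong regions missing from the combined list or from a replicate, the removal of these regions or of regions narrower than 50 bp, and the limit of 0.001 on the q-value were chosen after seeing the data.

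Computations used Python 3.11.15 with numpy 2.4.6, pandas 2.3.3 and scipy 1.17.1. The code was tested on simulated data made from the real lists. Exact copies of 200 replicate 1 regions were planted in a randomly placed copy of the replicate 2 list, and all were found (100%). Identical regions must overlap, so this checks only that the code runs correctly. A planted difference of 15 percentage points in the recovery of chromosome I regions was estimated at -17.8, and 6% of runs without a difference gave a p under 0.05. Recovery was simulated independently for each region, so that share does not cover the dependence of neighbouring regions.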

Results

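The data comprised lists of HAM-1::EGFP binding regions from 2 ChIP-seq replicates of fed L1 larvae and a combined list, called by the authors with PeakSeq on the WS220 genome. Replicate 1 held 4749 regions, replicate 2 held 2247 and the combined list held 5713. Together the regions of each list covered 2.60 Mb, 1.26 Mb and 3.23 Mb, or 2.60%, 1.26% and 3.23% of the 100.2 Mb of chromosome that calls spanned. Most regions were narrow. The median width was 426 bp (interquartile range 320 to 606 bp) in replicate 1, 425 bp (349 to 596.5 bp) in replicate 2 and 438 bp (324 to 631 bp) in the combined list. Regions of 2000 bp or wider made up 2.13%, 2.31% and 2.33% of the lists in the same order, and the widest combined region reached 10361 bp. At the other end, 153 regions of replicate 1, 5 of replicate 2 and 183 of the combined list were narrower than 50 bp. Sequencing depth was unknown for every library.

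The first comparison asked how far the replicates bound the same regions. Nearly every region of replicate 2 lay at a replicate 1 region: 2178 of 2247, or 96.9% (95% interval 96.1 to 97.6%). Random placement of the replicate 1 regions gave 5.16% on average and 6.68% at most (one-sided permutation p = 0.001, the smallest that 1000 placements can give). In the other direction 2148 of the 4749 replicate 1 regions, or 45.2% (43.8 to 46.7%), were overlapped in replicate 2, against 2.49% by random placement (permutation p = 0.001). The lists differed in length. When replicate 1 was reduced to its 2247 strongest regions, 80.7% of them were overlapped in replicate 2 and 82.2% of replicate 2 regions were overlapped in replicate 1.

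In replicate 1, recovery fell from the strongest regions to the weakest. All 475 regions of the strongest decile of replicate 1 were found in replicate 2, as were 96.6% of the second decile and 85.3% of the third. In the fifth decile 40.4% (36.1 to 44.9%) were found and in the weakest 2.95% (1.77 to 4.90%). The 2601 replicate 1 regions without a partner had a median q-value of 0.000727 and a median width of 354 bp, against 6.31e-11 and 528 bp for the 2148 regions with one. Replicate 1 regions narrower than 50 bp were almost wholly unshared, with 151 of the 153 lacking a partner. Replicate 2 held only 5 such regions, of which 3 lacked one. Broad regions were mostly shared, and 92 of the 101 replicate 1 regions of 2000 bp or wider had a partner. A wide region meets the 1 bp rule more easily, and width was not compared at matched q-value, so it was not set apart from strength. In replicate 2, recovery in replicate 1 was 98.2% in the strongest decile, where the 4 strongest regions of the list were the ones missing, 100% in the second and the third, and 88.4% (83.5 to 92.0%) in the weakest.

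**Figure D1:**
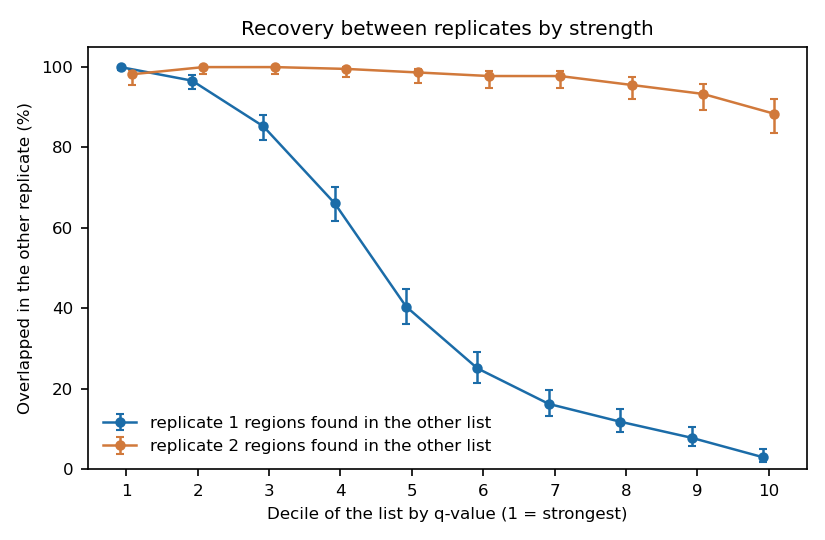
Share of each replicate's regions overlapped by 1 bp or more in the other replicate (y axis, percent) by decile of the list's q-value (x axis, 1 is strongest); bars are 95% Wilson intervals. Replicate 1 falls from 100% to 2.95%, while replicate 2 stays between 88.4% and 100%.

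Among the 2142 regions matched one to one, the ranking by q-value was largely shared (Spearman's rho = 0.81 across regions, two-sided permutation p = 1e-05, the smallest that 100000 permutations can give). Regions are not independent replicates, so this p describes the lists only. The q-value was lower in replicate 1 for 2062 of these regions, or 96.3%. The median −log10 q was 10.2 in replicate 1 and 4.396 in replicate 2. With depth unknown, this difference is one of call strength and does not measure binding.

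**Figure D2:**
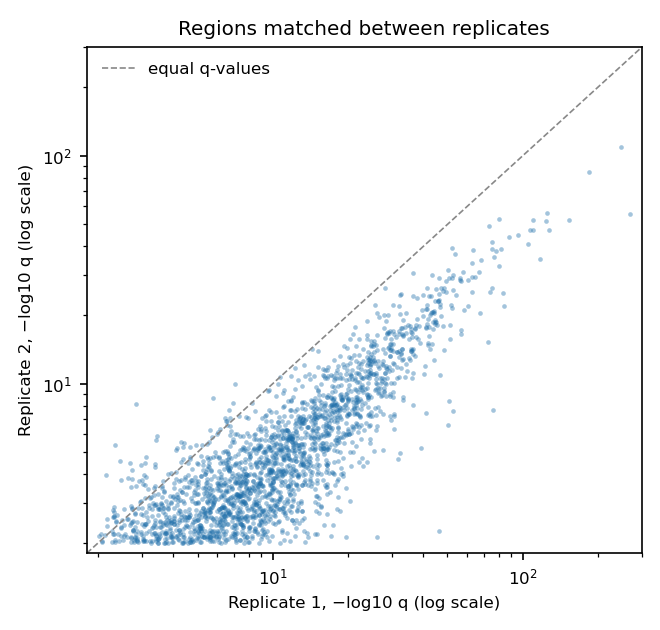
Each point is 1 of the 2142 regions matched between the replicates, with −log10 of its q-value in replicate 1 (x axis) and replicate 2 (y axis), both on log scales; the dashed line marks equal values. The points rise together (rho = 0.81) and 96.3% lie below the line.

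The second comparison asked which regions of the combined list both replicates held. Of its 5713 regions, 2125 or 37.2% (35.95 to 38.5%) overlapped regions of both replicates, 2391 or 41.9% overlapped replicate 1 only, 45 or 0.79% overlapped replicate 2 only, and 1152 or 20.2% overlapped neither. Support followed strength. All of the 500 strongest combined regions were in both replicates, as were 990 of the 1000 strongest. The median q-value was 6.67e-16 for regions in both replicates, 3.17e-05 for those in replicate 1 only and 0.00261 for those in neither. A few replicate regions were missing from the combined list, 187 of replicate 1 (3.94%) and 31 of replicate 2 (1.38%). These included the 2 strongest regions of replicate 1, on chromosome I from 5372259 to 5381936 and on chromosome III from 8443325 to 8447830, both of which replicate 2 also held.

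The 10 strongest combined regions held in both replicates lay on chromosomes I, II, IV, V and X, and they ranged in width from 753 to 10361 bp. The first, on chromosome II from 14403977 to 14408196, was 4220 bp wide with a q-value of 9.58e-261, and ranked 3 in replicate 1 and 6 in replicate 2. The second, on chromosome V from 6220812 to 6231172, was the widest region of the list at 10361 bp and ranked 4 and 11. The third lay on chromosome V from 19519472 to 19523198 (3727 bp, ranks 5 and 16). The strongest region on X ran from 1503453 to 1505306 (1854 bp) and ranked 6 and 7. Regions of over 2000 bp were also found on chromosome IV from 17276728 to 17281699 (4972 bp, ranks 12 and 20) and on chromosome I from 7079119 to 7086336 (7218 bp, ranks 30 and 93). The other 4 were under 1000 bp wide. They lay on chromosome I from 4171853 to 4172810 (ranks 7 and 12), on chromosome V from 9088536 to 9089310 (ranks 8 and 28), and on chromosome II from 5844497 to 5845249 (ranks 10 and 10) and from 11761569 to 11762409 (ranks 9 and 14). Their combined q-values ran from 9.63e-152 to 2.08e-132. The genes at these positions were not analysed here.

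The third comparison asked how the regions were spread over the genome. Chromosome III was the most densely bound and chromosome V the least, in the combined list and in replicate 1. Chromosome III carried 74.2 combined regions per Mb, 1.301 times its share of the span, and the ratio was 1.33 in replicate 1 and 1.34 in replicate 2. Chromosome V carried 45.7 combined regions per Mb, a ratio of 0.80, with 0.81 and 0.82 in the replicates. Both departures passed the exact binomial test with Benjamini-Hochberg adjustment in every list (in the combined list p = 1.98e-18, adjusted 1.19e-17, for III and p = 3.48e-15, adjusted 1.04e-14, for V). Chromosomes III and V were also the highest and lowest per protein-coding gene, with 38.7 combined regions per 100 genes on III and 19.1 on V. Chromosomes II and IV did not depart from their share of span in the combined list (ratios 0.94 and 1.01, adjusted p = 0.0725 and 0.638, exact binomial test). In replicate 2 alone, chromosome IV did (ratio 1.21, adjusted p = 1.96e-05, exact binomial test).

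Chromosome I differed between the replicates. It held 16.4% (15.3 to 17.4%) of replicate 1 regions and 12.3% (10.99 to 13.7%) of replicate 2 regions, against 15.04% of the span. Its ratio was thus above 1 in replicate 1 (1.09, adjusted p = 0.0177, exact binomial test), below 1 in replicate 2 (0.82, adjusted p = 0.000298) and above 1 in the combined list (1.15, adjusted p = 8.05e-06). Replicate 2 recovered 267 of the 777 replicate 1 regions on chromosome I, or 34.4% (31.1 to 37.8%), and 47.4% of those elsewhere. Compared within deciles of replicate 1 strength, recovery on chromosome I was lower by 12.5 percentage points (difference -12.5, two-sided permutation p = 0.0001 within deciles, the smallest that 10000 permutations can give, adjusted p = 0.0003 over 6 chromosomes). By the same permutation test recovery was higher on chromosome IV by 7.60 points (adjusted p = 0.0003), on V by 3.20 points and on X by 2.95 points (both adjusted p = 0.033). In that permutation test the difference did not pass the threshold on II (0.87 points, adjusted p = 0.54) or III (-2.35 points, adjusted p = 0.0822). Without matching on strength the differences were 10.1 points on IV, 1.33 on X, 0.34 on II, 0.91 on III and -0.45 on V, so in this comparison the directions on III and V rested on the matching. The comparators of these 5 chromosomes included chromosome I. With chromosome I left out, the matched differences on V and X fell to 0.74 and 0.73 points and no longer passed the threshold (both adjusted p = 0.596, permutation test over 5 chromosomes). Recovery on IV stayed higher by 5.25 points and that on III was lower (difference -5.09 points, both adjusted p = 0.0005, same permutation test). The comparator of III still held chromosome IV, which had the highest recovery (53.5%). No comparison without IV was run, so the lower recovery on III may in part reflect IV. Without matching and without chromosome I, the differences were 7.85 points on IV, -1.77 on III, -3.14 on V and -1.24 on X.

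The X chromosome held fewer regions than its length would give and more than its genes would give. It carried 920 combined regions, 16.1% (15.2 to 17.1%), against 17.7% of the span (ratio 0.91, two-sided exact binomial p = 0.0017, adjusted p = 0.00254 over 6 chromosomes) and 13.7% of the protein-coding genes (ratio 1.18, p = 1.60e-07). The shortfall by length was 0.90 in replicate 1 (exact binomial p = 0.000872) and 0.93 in replicate 2, where it did not pass the threshold (p = 0.109). Nor did it among the combined regions held in both replicates (ratio 0.92, exact binomial p = 0.0934). The excess by genes was not particular to X. In the combined list the ratio to the share of genes was also above 1 on I (1.198), III (1.352) and IV (1.076). It was below 1 on II (0.831) and V (0.669), and V holds 25.01% of the protein-coding genes. No ratio without V was computed, so the excess on X may in part reflect the low ratio on V.

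On the autosomes, binding regions were denser in the central part of the chromosomes than in the outer parts, and on X they were not. Each chromosome was divided into 3 equal parts for this comparison. In C. elegans the autosome centres are known for low recombination and for many essential genes. The central parts of the autosomes carried 74.9 combined regions per Mb and the outer parts 49.7, a density 1.51 times higher in the centre. The outer parts held 57.0% (55.6 to 58.4%) of autosomal regions against 66.69% by random placement (two-sided permutation p = 0.001, the smallest that 1000 placements can give). The centre was denser on each of the 5 autosomes in each list. The ratio of central to outer density in the combined list ran from 1.38 on III to 1.72 on V, and the autosomes together gave 1.54 in replicate 1 and 1.64 in replicate 2. On X the ratio was 0.93 in the combined list, 0.92 in replicate 1 and 0.97 in replicate 2, and the outer parts held 68.2% (65.1 to 71.1%) of its combined regions. The difference between X and the autosomes was itself past the threshold (odds ratio of lying in an outer part 1.61, Fisher's exact p = 2.31e-10). Fisher's exact test also passed it in replicate 1 (odds ratio 1.67, p = 8.13e-10) and in replicate 2 (1.70, p = 8.89e-06).

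**Figure D3:**
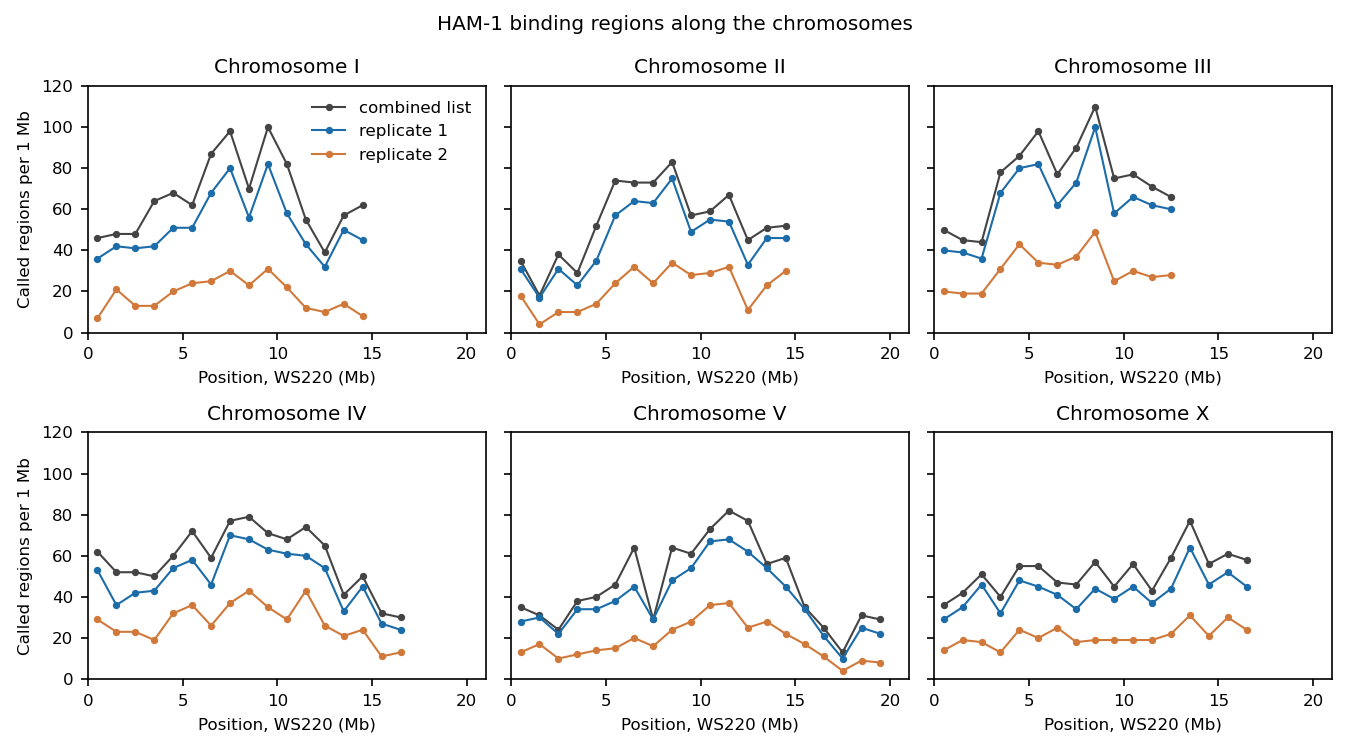
Number of called regions in each whole 1 Mb stretch (y axis) along the 6 chromosomes (x axis, WS220 position in Mb) for the combined list and each replicate. Counts are highest in the middle of the autosomes, reaching 110 combined regions on chromosome III, and show no such rise on X.

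Counts in 1 Mb stretches ranged widely and were shared by the replicates. Over 97 whole stretches the combined list had a median of 57 regions (interquartile range 45 to 71). The fullest was chromosome III from 8000001 to 9000000, with 110 combined, 100 replicate 1 and 49 replicate 2 regions. The emptiest was chromosome V from 17000001 to 18000000, with 13, 10 and 4. Chromosome II from 1000001 to 2000000 was next, with 18, 17 and 4. The counts of the replicates followed each other across stretches (Spearman's rho = 0.89, permutation p = 1e-05), although stretches are not independent samples. Neighbouring regions lay closer together than uniform random placement would give. Neighbouring midpoints were under 2000 bp apart for 14.3% of combined, 11.95% of replicate 1 and 6.60% of replicate 2 gaps, against 11.01%, 9.25% and 4.52% by random placement (one-sided permutation p = 0.001 in each list). The placement ignored the uneven density along the chromosomes, which alone raises the share of short gaps. Clustering at short range beyond that density was therefore not tested.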

Additional observations from a re-analysis of the deposited data

How the results depend on the processing

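Of 45 recomputed values, 37 kept their direction and their side of the threshold, or stayed within 1.5 times the main count; those that removed regions under 50 bp or the strong regions missing from the combined list, took q-values under 0.001, or concerned the recovery by chromosome or the contrast of X with the autosomes were chosen after seeing the data. Among these 45, the X share and the recovery of chromosome II were the results that reversed. Outside them, dropping the matching on strength also reversed the recovery differences of III (-2.35 to 0.91 points) and V (3.20 to -0.45). With chromosome I left out, it reversed those of V (0.74 to -3.14) and X (0.73 to -1.24). Set against X's share of protein-coding genes instead of its span, the ratio reversed from 0.91 to 1.18. Among regions in both replicates it was 0.92 and no longer past the threshold, and over each replicate's own list it ranged from 0.90 (past the threshold) to 0.93 (not past it). These are smaller lists at a similar ratio. Not every smaller list kept that ratio: in the stronger 50% of the combined list, with 2856 regions, it was 0.82 and past the threshold (exact binomial p = 4.43e-06). Under a 50% reciprocal overlap, combined regions supported by both replicates went from 37.2% to 32.7%, which follows from the stricter rule. The replicate overlap, the ranking, the autosome arm share and the contrast of X with the autosomes kept their call under every alternative run on them. For the replicate overlap the rule allowed no reversal and the permutation p stayed at 0.001 throughout, so an unchanged call there says little. Cutting replicate 1 to the length of replicate 2 moved its overlap from 45.2% to 80.7%. A q-value under 0.001 left 3498, 1578 and 4507 regions in replicate 1, replicate 2 and the combined list. With chromosome I left out of the comparators, matched recovery differences were no longer past the threshold on V (0.74 points) and X (0.73). The difference passed it on III (-5.09) and reversed on II (-1.70, not past the threshold on either side). Chromosome I's shortfall had lowered the comparators, and IV's higher recovery stayed in that of III. Recovery of chromosome I stayed between -9.84 and -13.5 percentage points. The planned ranking by another value per region was not run, since the lists hold only the q-value, nor were those of the promoter share, the gene lists and the sequence at region centres, which need an annotation or genome of the same build. No paired analysis was possible because the inputs have no values of their own here. Depth is unknown, so a region missing from replicate 2 was not called there, which does not show that it was unbound.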

Other observations

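The tests of the missing strong regions were chosen after the result was seen. No biological explanation was tested for any of these patterns, since all libraries are of one strain and stage.

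The strongest regions of both replicates were in part missing from the combined list. Within the 100 strongest regions of replicate 1, 5 had no combined counterpart, and they formed 3 stretches: chromosome I from 5372259 to 5381936, chromosome II from 10541889 to 10560050 and chromosome III from 8443325 to 8447830. Chosen by their rank in replicate 1, all 5 also overlapped a region ranked 171 of 2247 or better in replicate 2. The replicates largely shared their ranking, so this could hardly have differed. The combined list also kept 2391 regions that overlapped replicate 1 only. Weak evidence in replicate 2 thus did not by itself keep a region out of the combined list. A limit on width is argued against for chromosome III, where the stretch was 4506 bp long and the combined list kept a region of 10361 bp, but stays open for chromosome I, where replicate 1 called 9678 bp, and for chromosome II, where it called 3 regions of 3797 to 6986 bp that span 18162 bp and that a combined call may have joined. Loss from the combined list in the liftover, a step that removed chosen stretches from it, or an excess of reads there in the input may also account for the pattern and was not tested.

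The 4 strongest regions of replicate 2 were absent from replicate 1 and from the combined list. They lay on chromosome X from 16929264 to 16932047, on III from 9050722 to 9055097, on V from 1803967 to 1806522 and on I from 15063996 to 15067645, with q-values from 6.81e-153 to 3.08e-118. Of the next 96 strongest regions of replicate 2, 0 (0%) were missing from replicate 1. The 4 were picked as the only regions missing from the strongest decile, so this outcome was known beforehand and is no separate test. That replicate 1 held these weaker regions argues against a lower depth or enrichment in replicate 1 as a whole. A difference between the libraries at repeated sequence, or in how repeats were filtered, may account for them and was not tested; the region on I is the last called on that chromosome, the end known to carry the ribosomal DNA array.

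Replicate 2 recovered fewer regions of chromosome I than of the other chromosomes. Weaker regions on chromosome I in replicate 1 are argued against, since the shortfall was -12.99 percentage points without and -12.5 with matching on strength. Leaving out each of 15 stretches of 1 Mb in turn left the shortfall between -12.1 and -13.04 points (highest permutation p = 0.0005). No single one of these stretches thus accounts for it. The fullest held 82 of the 777 regions, so this outcome could hardly have differed. Wider parts of the chromosome were not left out, so a wider stretch stays open. A chromosome-wide difference in the control library or in the caller's scaling may also account for the shortfall and stays open, as no read counts or input values were at hand.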
